A study of Mus musculus with 13 samples.

How the data were processed

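RNA was measured in early distal convoluted tubules dissected by hand from mouse kidneys, in 6 female and 7 male libraries. Per the labels, the dissected tubules were washed in buffered saline and lysed, total RNA was purified on columns, cDNA was made with the SMART-Seq HT kit and libraries with the Nextera XT kit. The deposited table holds expected counts per gene, which per the labels were estimated by Salmon 0.14.10 with genome build GRCm38.p6. The step from transcripts to genes, the annotation release, the strandedness and any filter applied by the authors are not given in the sources used here. The values were checked: none is negative, and between 41.2% and 57.9% of the values of a library are not whole numbers, which fits expected counts. The 13 columns of values were all used. They were rounded to whole counts, which moves a count by at most 0.5. Of 54331 gene identifiers, 54097 were found in the GENCODE M21 annotation, from which symbols, biotypes and coordinates were taken, and 234 were not.

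Samples were grouped by the sex in their labels, and the comparison was of females against males. In edgeR 4.0.16 (R 4.3.3) genes were filtered with filterByExpr on the sex groups, which left 35104 genes, libraries were scaled by TMM, and a quasi-likelihood model with robust dispersions and sex as its term was fitted to the counts. Genes were called at an adjusted p of 0.05 (two-sided quasi-likelihood F-test, Benjamini-Hochberg over all tested genes). The square root of the common dispersion was 0.481. Fold changes are log2 of females over males, with their SE, so that negative values are higher in males. CPM are TMM-scaled and given as mean ± SD over n = 6 female and n = 7 male libraries, unless another n is stated. Total counts per library ran from 47839817 to 89075982. The chi-square per degree of freedom between any 2 libraries of a sex was at least 19.4, so no library was a second reading of another.

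Genes were named by a rule: every measured member of the Y-linked and X-escape lists and Xist; the 12 largest changes in each direction among called genes with a mean of at least 5 CPM in 1 sex and a proper name; 20 transport, signalling and hormone receptor genes of the segment, whatever their result; and from each list up to 4 called members, or the 2 with the highest mean CPM where none was called. The rule gave 98 distinct genes. Only 2 genes were eligible among those higher in females and 22 among those higher in males. Results of 2 of the 20 are left out of the text and of the figure. A further 23 genes were named after their values were seen.

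Sex labels were checked by the counts of Xist and of Y-linked genes. Lists were tested with camera on voom values (limma 3.58.1), two-sided, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 32 lists, and beside it with an estimated correlation and with fry. The estimated correlation and fry were used only with all libraries and without a covariate. List calls with a covariate or with libraries left out rest on the preset correlation. The 14 cell type lists covered early distal convoluted tubule, late distal convoluted and connecting tubule, principal, intercalated, thick ascending limb, macula densa, proximal tubule, proximal tubule genes known to be higher in males or in females, podocyte, endothelial, stromal, immune and red blood cell markers. The other lists were Y-linked and X-escape genes, regulators of the sodium chloride cotransporter, magnesium and calcium handling, hormone receptors, corticosteroid targets, clock, early response, interferon, cholesterol synthesis, fatty acid oxidation, glycolysis, endoplasmic reticulum stress, glutathione and redox, nuclear and mitochondrial respiratory chain and ribosomal protein genes. For each cell type list the CPM of its members were summed per library, and the mean of log2 of the sum plus 1 was compared between the sexes by a two-sided exact permutation test over all 1716 splits of 6 against 7 libraries, with Benjamini-Hochberg adjustment over the 14 lists.

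The rate of reads per kb on 1485 autosomal olfactory, vomeronasal and taste receptor genes is called the background here. These genes were taken to be silent in kidney, without a limit on their level. Among them Olfr54 stood at 2.55 CPM in females and 8.26 CPM in males and was itself called between the sexes. Correlations across libraries are Pearson's r and Spearman's rho with permutation p. They form a family of 3 relations.

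The alternatives were DESeq2 1.42.0, limma voom, median-of-ratios size factors, upper-quartile factors, library totals, no filter on counts, a filter of 5 CPM in 6 libraries, a replicate block, the proximal marker mean as a covariate, 1 surrogate variable (sva 3.50.0), a 1.5-fold threshold (glmTreat) and each library left out in turn. The design, the lists, the naming rule and these alternatives were fixed before the data were examined. Added after seeing the data were the background as a covariate, a covariate that sets libraries with label numbers 1 to 3 against the others (the number group), TMM factors from genes at 5 CPM, the omission of the libraries with the highest and lowest background, and the 5 CPM filter for the lists.

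The tests were checked on simulated data made from this table, with 50 genes changed at each of 4 sizes. At adjusted p 0.05 (Benjamini-Hochberg), edgeR recovered 18% of genes changed 2-fold, 96% at 4-fold, 96% at 8-fold and 100% at 16-fold, with 13 unchanged genes among 168 calls. DESeq2 recovered 42%, 100%, 100% and 100%, with 49 unchanged genes among 220 calls. limma voom recovered 22%, 88%, 98% and 100%, with 8 unchanged genes among 162 calls. Reads were not realigned, and isoforms and the tdTomato sequence were not analysed here.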

Results

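Early distal convoluted tubules, the part of the nephron where the thiazide-sensitive cotransporter Slc12a3 takes up sodium chloride, were collected from kidneys of female and male mice. The mice carried a Pvalb-tdTomato transgene, in which sequence of the parvalbumin gene, a marker of this segment, drives a red fluorescent protein. RNA of 6 female and 7 male libraries was sequenced, and the series title places the question in a comparison of this segment between the sexes. Total counts per library ran from 47839817 in female 4 to 89075982 in male 1. Between the sexes total counts differed with a two-sided exact permutation p = 0.0385, which missed the threshold after Benjamini-Hochberg adjustment over 7 library measures (adjusted p = 0.135). Mitochondrial genes took 14.9% ± 2.68 of the counts in females (SD, n = 6) and 15.2% ± 0.558 in males (SD, n = 7).

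All 13 libraries carried the sex given in their labels. Xist, the noncoding RNA that coats the inactive X chromosome, was counted 1903 to 4535 times in each female library and 19 to 102 times in each male library. This is 42.1 ± 15.2 CPM against 0.998 ± 0.371 CPM. The Y-linked RNA helicase gene Ddx3y stood at 0.211 ± 0.0779 CPM in females and 25.1 ± 7.62 CPM in males. Eif2s3y, which encodes a subunit of a translation initiation factor, stood at 0.493 ± 0.171 and 35.4 ± 12 CPM. Usp9y was counted 1 time in the female libraries together and 203 times in the male libraries. Single male libraries had between 1 and 49 counts, so this gene alone does not mark every male library. In edgeR (quasi-likelihood, Benjamini-Hochberg) Xist (ENSMUSG00000086503, X: 103460366 to 103483254) was higher in females by 5.39 ± 0.31 (log2, SE; adjusted p = 7.02e-10). By the same test Ddx3y (ENSMUSG00000069045, Y: 1260771 to 1286629) changed by -6.88 ± 0.32 (adjusted p = 5.85e-11) and Eif2s3y (ENSMUSG00000069049) by -6.15 ± 0.30 (adjusted p = 7.13e-11).

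The Y-linked genes Uty and Kdm5d carried reads in both sexes. Uty stood at 17.8 ± 5.35 CPM in females and 28.7 ± 3.93 CPM in males, and Kdm5d at 25.1 ± 6.63 and 30.1 ± 7.46 CPM, although females have no Y chromosome. Both genes have close relatives on the X chromosome, Kdm6a and Kdm5c, so their values and those of the relatives are uncertain, since shared reads cannot be assigned to one copy here. Of the 5 measured Y-linked members 3 fell in females over all genes, and 4 when adjusted over the list alone (edgeR, Benjamini-Hochberg). With 1 library left out, Uty was called only without female 5. The list as a whole was lower in females (median -6.15, camera adjusted p = 5.27e-15), with an adjusted p = 0.000151 with an estimated correlation.

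**Figure D1:**
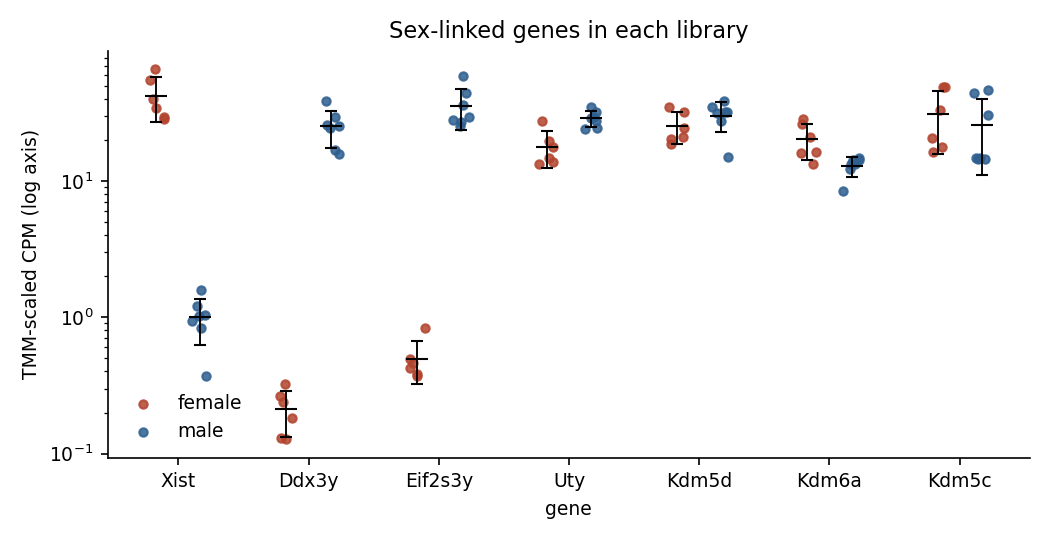
TMM-scaled CPM (log axis) of 7 sex-linked genes in each of the 6 female and 7 male libraries, with the mean and SD. Xist lies between 28.3 and 65.8 CPM in females and below 1.60 CPM in males, while Uty and Kdm5d, which resemble Kdm6a and Kdm5c on the X chromosome, carry reads in both sexes.

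Genes that escape X inactivation leaned towards females. The 7 members all had positive fold changes, with a median of 0.27 (camera adjusted p = 0.0162, and adjusted p = 0.236 with an estimated correlation), and the call ended without female 1, 2 or 3 and without male 4 or 5. None passed over all 35104 genes, and 1 passed when adjusted over the list alone, the histone demethylase gene Kdm6a (0.64 ± 0.21, edgeR adjusted p = 0.429 over all genes). The translation factor gene Eif2s3x stood at 56.1 ± 16 CPM in females and 39.9 ± 9.29 CPM in males. Among genes of at least 5 CPM in 6 libraries it rose in females by 0.71 ± 0.11 (edgeR adjusted p = 0.00585), and the median of the list was 0.55 (camera adjusted p = 6.60e-07, and adjusted p = 0.00502 with an estimated correlation).

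Outside the sex chromosomes few genes were called between the sexes in the fit without a covariate, and those higher in males included transporters and enzymes of the proximal tubule. Of 35104 genes tested, 189 were called (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), 10 higher in females and 179 higher in males, and 2386 had an unadjusted p under 0.05. The calls included 144 of 173 tested Y-linked genes, 6 of 1160 X-linked genes, 35 of 33641 autosomal genes and 4 genes outside the annotation. DESeq2 called 509 genes and limma voom 144. The edgeR count was 124 without male 3, 122 without male 4, 114 without male 5 and 114 without male 7.

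Of the 144 Y-linked calls, 137 were gene models without a proper name. Among the named ones with a mean of at least 5 CPM in males the largest change was in Sly, a gene of developing sperm, at 0.0361 ± 0.0371 CPM in females and 6.13 ± 1.37 CPM in males (-7.38 ± 0.49, edgeR adjusted p = 5.17e-09). Among the 7 male libraries, the rate of reads per kb on the 141 called Y genes outside the Y-linked list followed the background on silent autosomal receptor genes with r = 0.996 (exact permutation p = 0.000198, adjusted p = 0.000298 by Benjamini-Hochberg over 3 relations). Spearman's rho was 1 (exact permutation p = 0.000397). Without the 2 libraries farthest from the median background r was 0.98. The ratio of both rates was 2.64 ± 0.134 (SD, n = 7) in males and at most 0.0408 in females.

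X-linked calls were Xist, Gata1, Frmpd3, 5330434G04Rik and Gm15256, higher in females, and 4933407K13Rik, higher in males. Apart from Xist these were chosen after their values were seen. Gata1, a transcription factor gene of blood cell precursors, stood at 1.98 CPM in females and 0.619 CPM in males, and Frmpd3 at 3.21 and 1.28 CPM, while 4933407K13Rik stood at 4.42 and 13.3 CPM. Frmpd3 lost its call without female 4 or 6 or male 2, 6 or 7, 5330434G04Rik kept it only without female 3, male 1 or male 6, and Gm15256 only without female 2, 3 or 4 or male 1. A total of 387 X-linked genes had an unadjusted p under 0.05, and DESeq2 called 88 X-linked genes. Of the calls outside the annotation, ENSMUSG00000118461 had the highest level, 0.404 ± 0.201 CPM in females and 46.4 ± 12.7 CPM in males. ENSMUSG00000118447 was also higher in males, and ENSMUSG00000118488 (not called without female 4 or male 2, 3, 4 or 5) and ENSMUSG00000118511 were higher in females. The positions of these 4 genes, singled out after their values were seen, are not given in the sources used here.

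Females had higher levels of 3 autosomal genes. P2ry1 (ENSMUSG00000027765, 3: 61002795 to 61008982), which encodes a receptor for extracellular ADP, stood at 63.6 ± 14.7 CPM in females and 30.6 ± 10.3 CPM in males. It changed by 1.05 ± 0.23 (edgeR adjusted p = 0.035), and all 6 female libraries lay above every male library. Ncf4 (ENSMUSG00000071715, 15: 78244801 to 78262580), which encodes a subunit of the NADPH oxidase of phagocytes, stood at 22.6 ± 10.8 and 7.07 ± 3.11 CPM, 3.2-fold (1.68 ± 0.37, edgeR adjusted p = 0.0363). The long noncoding RNA gene Gm49694 (ENSMUSG00000116697, 15: 78174461 to 78174851), named after its values were seen, stood at 37.0 ± 16.6 and 9.24 ± 3.53 CPM (2.00 ± 0.34, edgeR adjusted p = 0.00269). Ncf4 and Gm49694 lie on either side of Pvalb (15: 78191114 to 78206400), at 38.4 kb and 16.3 kb, and Pvalb itself was not called (-0.42 ± 0.26, edgeR adjusted p = 0.651). Of the 28 alternatives, P2ry1 kept its call in 12 (with 1 library left out, only without female 1 or 5 or male 1, 4 or 7), Ncf4 in 8 (only without female 1 or 4 or male 1) and Gm49694 in 23 (whichever library was left out). With only genes of at least 5 CPM none of the 3 was called (fold changes of 1.31, 1.76 and 2.11, adjusted p = 0.104, 0.284 and 0.0857, edgeR), nor with the background on silent receptor genes as a covariate, chosen after seeing the data.

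Males had higher levels of 32 autosomal genes, and 6 of the 35 autosomal calls were on the proximal tubule lists. Ugt2b38 (ENSMUSG00000061906, 5: 87409942 to 87424203), a gene of the glucuronosyltransferase family, stood at 0.446 ± 0.224 CPM in females and 9.97 ± 7.95 CPM in males, 22.3-fold (-4.48 ± 0.51, edgeR adjusted p = 1.34e-05). Cyp2e1 (ENSMUSG00000025479, 7: 140763739 to 140774987), a cytochrome P450 gene, stood at 1.83 ± 0.722 and 16.9 ± 14.2 CPM, 9.23-fold (-3.21 ± 0.46, edgeR adjusted p = 0.000289). In both genes all 7 male libraries lay above every female library. Ugt2b38 and the carboxylesterase genes Ces2c and Ces1f have near-identical family members, so their levels are uncertain. The other largest changes were the amino acid transporter gene Slc7a13 (-2.89), the organic anion and urate transporter genes Slc22a6 (-2.86) and Slc22a12 (-2.67), Ces2c (-3.19) and Ces1f (-2.52). They also included the medium-chain acyl-CoA synthetase gene Acsm2 (-2.75), the phosphate transporter gene Slc34a1 (-2.71), the scaffold gene Pdzk1 (-2.42) and the argininosuccinate synthase gene Ass1 (-2.28). Adjusted p of these 9 genes lay between 0.00305 and 0.0447 (edgeR). With 1 library left out, calls ended for Slc22a6 (male 1), Ces2c (female 5 or male 1), Ass1 (female 4) and Slc34a1 (female 3 or 4 or male 5). Slc7a13 kept its call only without male 2, 3, 4 or 6, Slc22a12 only without female 4 or male 2, 3, 4 or 6, and Ces1f only without female 4 or 5 or male 1, 2, 3 or 6. With the background as a covariate, chosen after seeing the data, 6 of the 35 autosomal calls were kept, none of them on the proximal tubule lists, and of the genes above Ugt2b38 alone stayed called. With label numbers 1 to 3 against the others as a covariate, also chosen after seeing the data, 19 of the 35 were kept, and the calls of Slc7a13, Slc22a12, Slc34a1, Acsm2, Ass1, Ces2c and Ces1f ended.

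With only the 12867 genes of at least 5 CPM in 6 libraries, 27 genes were called (edgeR, Benjamini-Hochberg), 20 of them on Y, 2 on X (Xist and Eif2s3x), 4 on autosomes and 1 outside the annotation. The autosomal genes were Cyp2e1, the unnamed gene Gm37924 (ENSMUSG00000102482, 3: 28879812 to 28883458), Ppp1r1b and Sostdc1, of which the last 3 were chosen after their values were seen. With the proximal marker mean as a covariate 3 autosomal genes passed, Cyp2e1 (-1.97, adjusted p = 0.0212, edgeR), Ugt2b38 (-3.42, adjusted p = 0.0182) and Gm37924 (-2.61, adjusted p = 0.000614).

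Genes on the marker lists of neighbouring cell types were counted in all libraries. The sums of the thick ascending limb list, which is mostly 1 gene, and of the proximal tubule and immune lists were higher in the male libraries. The thick ascending limb, which leads into the distal convoluted tubule, had summed markers of 7958 ± 1850 CPM in females and 13122 ± 2460 CPM in males, 1.66-fold. Folds of these sums are of the means of log2 of the sum plus 1, not of the mean CPM. All 7 male libraries lay above every female library (two-sided exact permutation p = 0.000583, the smallest the 1716 splits can give, adjusted p = 0.00816 by Benjamini-Hochberg over 14 lists). Most of that sum came from uromodulin, Umod, at 7552 ± 1828 and 12542 ± 2259 CPM (-0.73 ± 0.23, edgeR adjusted p = 0.367 over all genes), so its test is largely one of Umod. By itself it does not show more RNA of this limb in males. Whether the Umod reads came from that limb or from the dissected segment was not tested. Slc12a1, another marker of this limb, ran from 54.5 to 703 CPM in females and from 54.0 to 697 CPM in males (-0.41, edgeR adjusted p = 0.796). Of the 9 measured members 7 had negative fold changes. Proximal tubule markers not chosen for a sex difference summed to 157 ± 93.3 and 478 ± 326 CPM, 2.82-fold (exact permutation p = 0.0128, adjusted p = 0.0449 by Benjamini-Hochberg), with 4 male libraries above every female library. Proximal tubule genes known to be higher in male mice summed to 46.5 ± 24.2 and 357 ± 455 CPM, 4.61-fold (exact permutation p = 0.00991, adjusted p = 0.0449 by Benjamini-Hochberg). Most of the male sum came from 1 member, Kap, named after its values were seen. It stood at 12.2 ± 17.3 and 273 ± 422 CPM and was not called itself (edgeR adjusted p = 0.311 over all genes). Immune markers summed to 579 ± 316 and 1167 ± 313 CPM, 2.26-fold (exact permutation p = 0.00641, adjusted p = 0.0449 by Benjamini-Hochberg). In each of the last 2 lists 5 male libraries lay above every female library.

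Early distal convoluted tubule markers summed to 16940 ± 5589 CPM in females and 22823 ± 8550 CPM in males (exact permutation p = 0.165, adjusted p = 0.33 by Benjamini-Hochberg). Late distal convoluted and connecting tubule markers summed to 6485 ± 1809 and 7230 ± 3437 CPM (exact permutation, Benjamini-Hochberg adjusted p = 0.814). The other 8 sums also missed the threshold, with adjusted p from 0.206 to 0.867 (exact permutation, Benjamini-Hochberg). Among them were podocyte markers at 44.0 and 33.5 CPM, endothelial markers at 419 and 453 CPM and red blood cell markers at 1.47 and 1.46 CPM. The thick ascending limb sum stayed called with each library left out, and lost its call with library totals (-0.43, exact permutation p = 0.00524, adjusted p = 0.0734). The proximal sum stayed called only without female 5, male 2 or male 6. The male-biased proximal sum did so only without male 3, male 5 or male 6, and the immune sum only without female 3, female 6, male 1, male 5 or male 6 (exact permutation tests with Benjamini-Hochberg adjustment). The macula densa sum was called only without male 5.

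**Figure D2:**
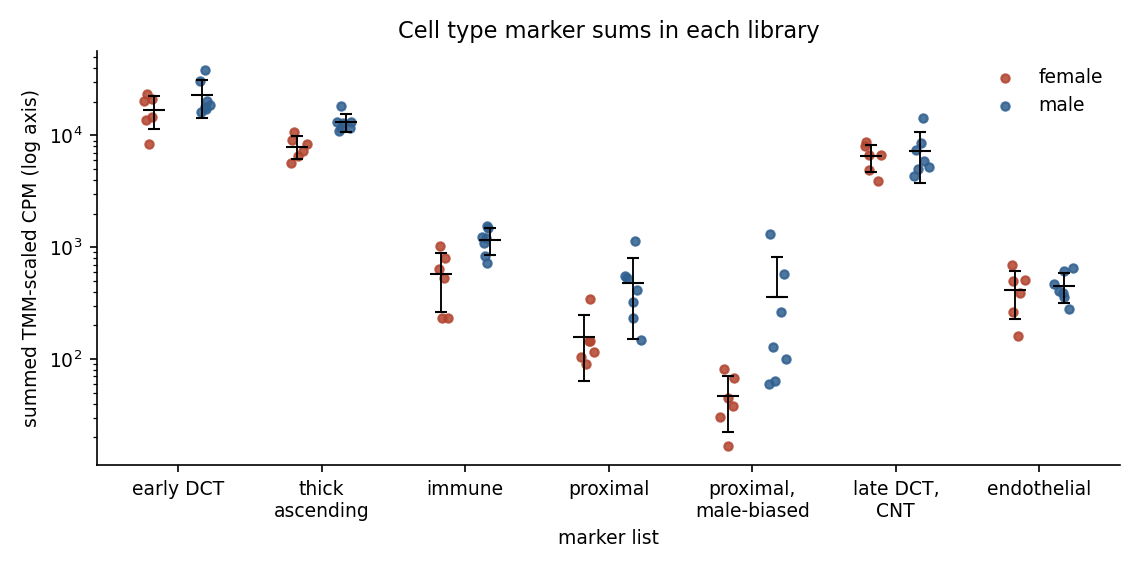
Summed TMM-scaled CPM (log axis) of 7 marker lists in each of the 6 female and 7 male libraries, with mean and SD (the lower bar is left out where the SD exceeds the mean). The thick ascending limb sums of the males (10940 to 18338 CPM) all lie above those of the females (5618 to 10728 CPM), and male 1 is the highest library for 5 of the lists.

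In the proximal tubule list, 2 of 15 markers fell in females over all genes, Acsm2 (8.47 ± 2.80 CPM in females, 56.8 ± 50.4 CPM in males) and Slc34a1 (8.68 ± 4.28 and 56.9 ± 52.5 CPM), and 10 when adjusted over the list alone (edgeR, Benjamini-Hochberg). The list median was -1.30 (camera adjusted p = 4.23e-11, and adjusted p = 0.236 with an estimated correlation). Among the 11 genes known to be higher in males, 4 fell in females over all genes, Cyp2e1, Slc7a13, Cyp4a12a (-3.68, uncertain because of its near-identical copy) and the organic anion transporter gene Slco1a1 (-2.95, called with 1 library left out only without female 5 or male 2). When adjusted over the list alone 9 fell in females (edgeR; median -1.66, camera adjusted p = 1.04e-09, and adjusted p = 0.236 with an estimated correlation). The 3 genes known to be higher in females all had positive fold changes (median 0.56, camera adjusted p = 0.0137, and adjusted p = 0.236 with an estimated correlation). Of these 0 passed over all genes and 1 when adjusted over the list alone (edgeR), the amino acid transporter gene Slc7a12, at 0.379 CPM in females and 0.0786 CPM in males. Of 15 immune markers, 0 passed over all genes and 11 fell in females when adjusted over the list alone, among them Cd74 (-1.03 ± 0.33) and H2-Ab1 (-1.13 ± 0.33), which present antigens (edgeR). The immune list was lower in females (median -0.97, camera adjusted p = 4.27e-12, and adjusted p = 0.236 with an estimated correlation). In the thick ascending limb list, 0 of 9 passed over all genes and 2 fell when adjusted over the list alone, Umod and Ppp1r1b (median -0.62, camera adjusted p = 0.00182, and adjusted p = 0.236 with an estimated correlation). With the background as a covariate the thick ascending limb call ended (median on voom values -0.09, camera adjusted p = 0.0515), and the median of the female-biased proximal genes was 0.07 (camera adjusted p = 0.0485).

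The genes that move salt, magnesium and calcium in this segment did not pass the test for a difference between the sexes. Slc12a3 (ENSMUSG00000031766, 8: 94329201 to 94366214) stood at 8233 ± 2961 CPM in females and 10817 ± 4137 CPM in males (-0.39 ± 0.29, edgeR adjusted p = 0.651). Its regulators Wnk4 (-0.45 ± 0.34), Stk39 (-0.44 ± 0.31), Wnk1 (-0.22 ± 0.25) and Klhl3 (-0.26 ± 0.41) were not called either. The magnesium channel gene Trpm6 had a fold change of 0.05 ± 0.25, Egf -0.58 ± 0.28 and Cnnm2 -0.22 ± 0.24. The calcium-binding and transport genes Calb1, Slc8a1 and Trpv5 had 0.13 ± 0.29, 0.18 ± 0.34 and -0.92 ± 0.94. For the basolateral channel genes Kcnj10 and Kcnj16 the values were -0.28 and -0.23, and for Nr3c2 and Hsd11b2, the mineralocorticoid receptor and the enzyme that protects it, -0.38 and -0.82. Only Egf and Nr3c2 among these genes kept their sign in all 28 alternatives. With library totals, which move the median of all genes from 0.13 to 0.40, the signs of Wnk1, Klhl3, Cnnm2, Kcnj10 and Kcnj16 turned, while relative to that median they stayed negative (-0.30, -0.29, -0.40, -0.34 and -0.34). With the background as a covariate the signs turned for Slc12a3, Wnk4, Stk39, Wnk1, Klhl3, Trpv5, Kcnj10, Kcnj16 and Hsd11b2. With the proximal covariate those of Trpm6, Calb1, Slc8a1 and Trpv5 turned, and several turned in other alternatives.

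**Figure D3:**
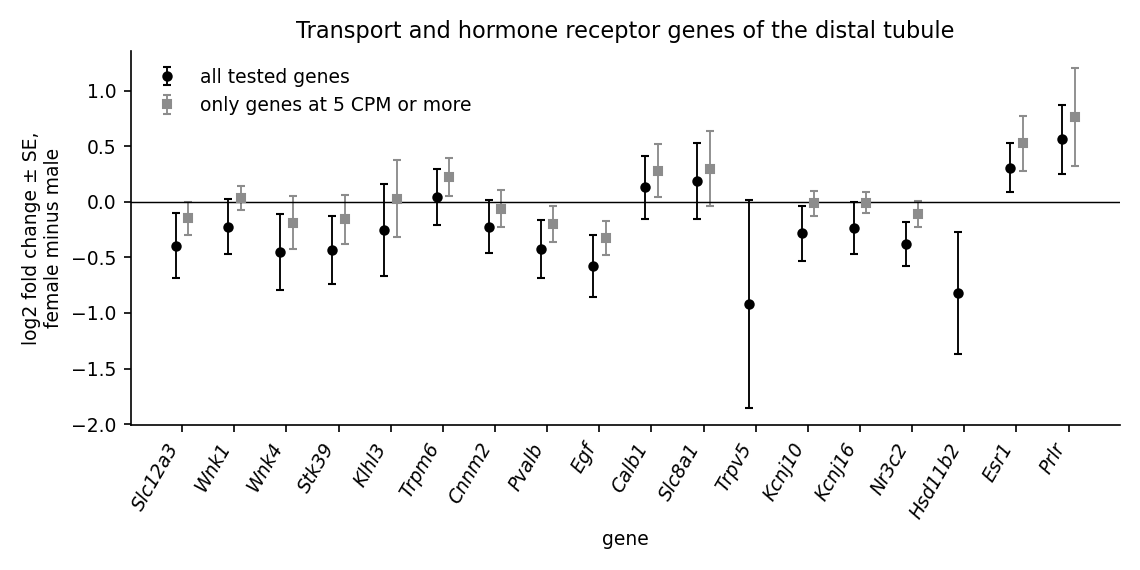
Log2 fold change (females over males) with SE of 18 transport, signalling and hormone receptor genes, in the fit of all tested genes (black) and in the fit of genes of at least 5 CPM in 6 libraries (grey, left out where a gene is below it). No gene passed in either fit, and Slc12a3 moved from -0.39 to -0.15 between them.

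Over all genes none of the 10 early distal convoluted tubule markers, 22 regulators of the cotransporter, 13 magnesium genes or 13 calcium genes was called, nor when adjusted over the list alone (edgeR, 0 in each list). Medians of the markers and the regulators were -0.33 (camera adjusted p = 0.00119, and adjusted p = 0.398 with an estimated correlation) and -0.30 (camera adjusted p = 0.000124, and adjusted p = 0.398 with an estimated correlation). Those of the magnesium and calcium genes were -0.20 (camera adjusted p = 0.00538, and adjusted p = 0.398 with an estimated correlation) and -0.22 (not called, camera adjusted p = 0.0772). These medians sit beside a median of 0.13 over all tested genes, which is -0.22 among genes of at least 5 CPM and 0.30 among the others. With the background on silent receptor genes as a covariate, chosen after seeing the data, the camera direction turned for all 4 lists, with medians on voom values of 0.11 for the regulators (adjusted p = 0.0186) and 0.14 for the calcium genes (adjusted p = 0.0293), both then called higher in females, and of 0.04 for the markers (adjusted p = 0.291) and -0.06 for the magnesium genes (adjusted p = 0.454), not called. Without the libraries with the highest and lowest background camera called none of the 4 (adjusted p from 0.396 to 0.755). Both settings used the preset correlation alone. With library totals, which shift all genes, the medians of the regulators, magnesium and calcium genes turned positive but stayed at -0.38, -0.29 and -0.32 relative to the median of all genes, and the magnesium call ended without female 4 or male 1. The calcium genes were called lower in females without female 1, 2, 3 or 6 or male 5 or 7 and with label numbers 1 to 3 against the others as a covariate, chosen after seeing the data (median on voom values -0.26, camera adjusted p = 0.0342), and the magnesium and calcium medians turned positive with TMM factors from genes at 5 CPM and with the 5 CPM filter. The median of all genes was 0.03 with median-of-ratios factors, 0.21 with upper-quartile factors, 0.40 with library totals and 0.34 with TMM factors from genes at 5 CPM. Relative to the median of all genes, the signs of the endothelial, stromal, calcium and clock lists turned with the 5 CPM filter.

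Hormone receptors were measured at levels that differed widely. The oestrogen receptor gene Esr1 stood at 6.37 ± 1.71 CPM in females and 5.15 ± 0.924 CPM in males (0.31 ± 0.22) and the prolactin receptor gene Prlr at 7.81 ± 2.64 and 5.28 ± 2.10 CPM (0.56 ± 0.31). Vdr and Pth1r, the receptors for vitamin D and parathyroid hormone, had fold changes of -0.24 and -0.11. Signs of both turned with library totals (-0.34 and -0.21 relative to the median of all genes) and with the background as a covariate, and that of Pth1r also with TMM factors from genes at 5 CPM and with the 5 CPM filter. Of 21 receptors, 0 passed over all genes, and 2 passed when adjusted over the list alone (edgeR), among them the vasopressin receptor gene Avpr2, higher in males (-1.84). With 1 library left out, Avpr2 was called only without female 5. The receptor list was not called (median -0.11, camera adjusted p = 0.0955), except without female 1 or 2 and with the replicate block. Its median was positive with library totals and with TMM factors from genes at 5 CPM, which shift all genes. Relative to the median of all genes it stayed at -0.21 and -0.25. Avpr2 is also on the principal cell list, where it was the 1 of 7 members to pass when adjusted over the list alone, against 0 over all genes (edgeR). The principal cell list was lower in females (median -0.73, camera adjusted p = 0.0162, and adjusted p = 0.326 with an estimated correlation), and its call ended without male 1 and with the background as a covariate (median on voom values 0.04, camera adjusted p = 0.988).

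Genes of energy metabolism and protein synthesis lay lower in females as groups in camera with a preset correlation, by small amounts and without calls of single genes over all genes. Of 82 nuclear genes of the respiratory chain, 79 had negative fold changes with a median of -0.62 (camera adjusted p = 7.04e-32, and adjusted p = 0.236 with an estimated correlation). None of them was called over all genes, and 50 fell in females when adjusted over the list alone (edgeR), while the ATP synthase genes Atp5b and Atp5a1 had fold changes of -0.42 and -0.45. Of 83 ribosomal protein genes 82 had negative values (median -0.56, camera adjusted p = 3.36e-28, and adjusted p = 0.288 with an estimated correlation). So had all 13 mitochondrially encoded genes (median -0.46, camera adjusted p = 5.19e-06, and adjusted p = 0.32 with an estimated correlation). Negative values were also found for 15 of 16 glycolysis genes (median -0.41, camera adjusted p = 5.82e-07, and adjusted p = 0.288 with an estimated correlation) and all 16 genes of fatty acid oxidation (median -0.40, camera adjusted p = 4.88e-06, and adjusted p = 0.356 with an estimated correlation). In these 4 lists 0 members passed over all genes and 0 when adjusted over the list alone (edgeR). Genes of at least 5 CPM had a median of -0.22 in the same fit, so the negative signs alone say little. With library totals the medians were -0.27 (nuclear respiratory chain), -0.22 (ribosomal), -0.11 (mitochondrially encoded), -0.11 (glycolysis) and -0.07 (fatty acid oxidation). Relative to the median of all genes these were -0.67, -0.62, -0.50, -0.50 and -0.46. Levels were highest in male 1 and lowest in female 4 for Atp5b (11920 and 2913.9 CPM) and Rps2 (782.2 and 182.1 CPM), and the other males had at most 8397.8 and 524.9 CPM. Male 1 and female 4 also had the lowest and highest TMM factors (0.579 and 1.591), by which CPM are scaled. With the background as a covariate, chosen after seeing the data, medians on voom values were -0.19 for the nuclear respiratory chain (camera adjusted p = 3.24e-12), -0.10 for ribosomal proteins (0.000212), -0.12 for glycolysis (0.0336), -0.06 for the mitochondrially encoded genes (0.508, not called) and -0.0043 for fatty acid oxidation (0.624, not called). Without the libraries with the highest and lowest background the fatty acid oxidation call ended (-0.09, camera adjusted p = 0.194), and the other 4 stayed.

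Cholesterol synthesis genes had a median of -0.41 with all 18 values negative (camera adjusted p = 4.66e-11, and adjusted p = 0.236 with an estimated correlation). Over all genes 0 were called and 2 were lower in females when adjusted over the list alone (edgeR), the sterol synthesis enzymes Lss and Dhcr7. Glutathione and redox genes had a median of -0.45 (camera adjusted p = 0.000106, and adjusted p = 0.333 with an estimated correlation). Interferon and antigen presentation genes had a median of -0.53 (camera adjusted p = 5.93e-06, and adjusted p = 0.32 with an estimated correlation) and endoplasmic reticulum stress genes -0.28 (camera adjusted p = 0.00734, and adjusted p = 0.398 with an estimated correlation). The stress gene median turned positive with library totals, which shift all genes, but stayed at -0.36 relative to the median of all genes. Its call ended without female 4 or male 1. With the background as a covariate the interferon call ended (median on voom values -0.21, camera adjusted p = 0.186), and the camera direction of the glutathione and stress genes turned, without calls (0.04, adjusted p = 0.818, and 0.04, adjusted p = 0.186). Without the libraries with the highest and lowest background the glutathione call ended (-0.05, camera adjusted p = 0.194) and the stress gene direction turned (0.04, adjusted p = 0.943). The cholesterol call stayed in both settings, which were chosen after seeing the data. No member of these 3 lists was called over all genes or when adjusted over the list alone (edgeR, 0 in each). Hspa1b of the early response list and the H2 genes of the interferon list have near-identical relatives, so their values are uncertain.

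The remaining lists were not called by camera in the fit of all libraries without a covariate, and none of their members was called over all genes or when adjusted over the list alone (edgeR). Clock genes had a median of 0.01 while the test pointed lower in females (adjusted p = 0.418), and intercalated cell markers a median of -0.55 while the test pointed higher (adjusted p = 0.659). Late distal convoluted and connecting tubule markers had a median of -0.45 (adjusted p = 0.34), corticosteroid targets -0.37 (0.364), early response genes -0.27 (0.232), endothelial markers -0.01 (0.202), stromal markers 0.03 (0.474), blood markers 0.26 (0.493), macula densa markers 0.33 (0.0572) and podocyte markers 0.51 (0.11). The sign turned with library totals for the intercalated, endothelial and early response medians, and with median-of-ratios factors for the clock median. Relative to the median of all genes none of these signs turned (-0.19, -0.22, -0.25 and -0.24). With the background as a covariate, chosen after seeing the data, camera called 5 of these lists higher in females: intercalated (median on voom values 0.73, adjusted p = 5.12e-05), late distal convoluted and connecting tubule (0.32, 0.00209), corticosteroid targets (0.48, 4.33e-07), clock (0.18, 0.00849) and early response (0.55, 1.29e-09). Without the libraries with the highest and lowest background it called higher in females the intercalated (0.62, adjusted p = 0.000308), late distal convoluted and connecting tubule (0.26, 0.0310), corticosteroid (0.31, 0.00536), early response (0.29, 0.00488) and podocyte (0.37, 0.0346) lists. Both settings used the preset correlation of 0.01 alone. In the fit of all libraries the estimated correlation was 0.63 (intercalated), 0.50 (late distal convoluted and connecting tubule), 0.65 (corticosteroid), 0.62 (early response), 0.27 (podocyte) and 0.11 (clock). With such estimates only the Y-linked list stayed called in that fit, so these calls may not hold. With 1 library left out, camera called the macula densa list (without female 3 or 5 or male 2 or 5), the podocyte list (female 4), the endothelial list (female 3), the intercalated list (male 1) and the early response list (female 2).

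In total, camera with a preset correlation called 20 of 32 lists, 18 of them lower in females, and with an estimated correlation only the Y-linked list stayed called, as with fry for 1 direction and for changes in either direction. Among genes of at least 5 CPM, 12 of 26 testable lists were called, 11 of them lower in females, and 2 with an estimated correlation, the Y-linked and X-escape lists.

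**Figure D4:**
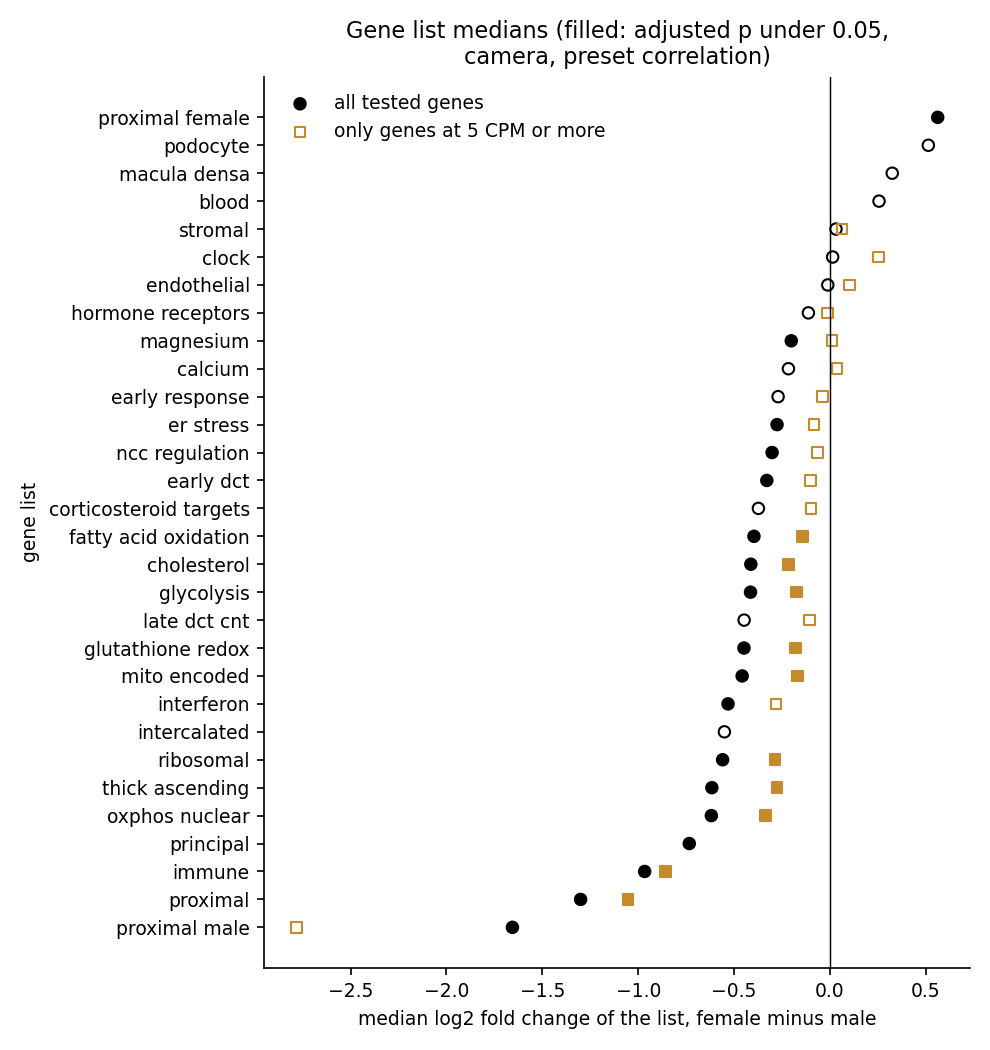
Median log2 fold change (females over males) of 30 gene lists over all tested genes (circles) and over genes of at least 5 CPM (squares), filled where camera with a preset correlation gave an adjusted p under 0.05. The nuclear respiratory chain median is -0.62 over all tested genes and -0.34 among genes of at least 5 CPM, and signs of some lists near 0 turn with the scaling.

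The largest difference among the libraries followed the reads on receptor genes taken to be silent in kidney. The first principal component held 51.3% of the variance and ran against the background on silent receptor genes with r = -0.976 (permutation p = 1e-05, the smallest that was possible, adjusted p = 3e-05 by Benjamini-Hochberg over 3 relations) and rho = -0.945 (permutation p = 3e-05). Without the 2 libraries farthest from the median background r was -0.954, and it was -0.95 within females and -0.998 within males. The background per kb ran from 0.247 CPM in male 1 to 3.18 CPM in female 4. The mean was 1.72 ± 0.806 CPM in females and 1.09 ± 0.469 CPM in males (exact permutation p = 0.104, adjusted p = 0.181 by Benjamini-Hochberg over 7 library measures). The TMM factors ran with it, from 0.579 in male 1 to 1.59 in female 4. The next component held 9% of the variance and differed between the sexes (exact permutation p = 0.0035). It was computed with Y-linked genes and Xist included, so a difference between the sexes is given by the design. Male 1 (45.28) lay within the range of the females (34.32 to 60.51) on it. A component without sex chromosome genes was not computed.

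**Figure D5:**
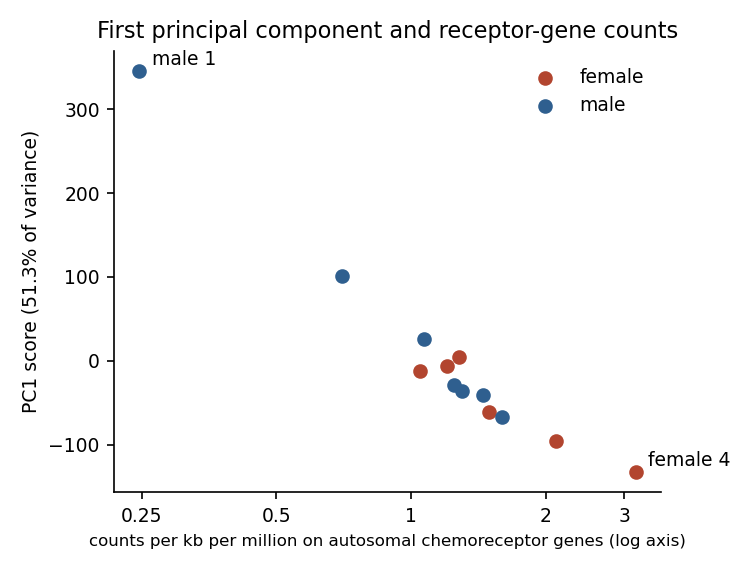
Score on the first principal component (51.3% of the variance) against the background, the CPM per kb on 1485 autosomal receptor genes (log axis), 1 point per library in 6 females and 7 males. Male 1 (0.247 CPM per kb) and female 4 (3.18 CPM per kb) lie at the ends.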

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

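The omission of the libraries with the highest and lowest background, the background covariate and both tests of the proximal tubule genes below were chosen after the results were seen, while the search for libraries that stand apart was fixed before. A library was picked out where its gap to the nearest other library of its sex was large against the range of that sex (Dixon's test at 95%). Of 284 groups of values checked, 41 had such a library, against 14.2 expected by chance, and 20 of the 41 were in male 1. The 14.2 holds for normal and independent values. CPM were not log-transformed here, and list sums were checked beside their own members, so it is only a rough guide.

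Male 1, the library with the most counts and the lowest background, lay far from the other males on the first principal component (345.6, others at most 101.5). Its TMM factor was the lowest (0.579), which raises its CPM against library totals, and how far this makes the values below was not tested. Its summed markers were the highest among males for the thick ascending limb (18338 CPM), the late distal convoluted and connecting tubule (14301), the proximal tubule (1137.7), the male-biased proximal genes (1301.8), intercalated cells (296.5) and principal cells (160.0). The early distal convoluted tubule sum was also highest in male 1 (38811 CPM), without being picked out by the rule. Among genes it was highest for Umod (17278 CPM), the kallikrein gene Klk1 (8527), the secreted glutathione peroxidase gene Gpx3 (2515), the androgen-regulated kidney gene Kap (1176), the ribosomal protein gene Rps2 (782.2), the vitamin D receptor gene Vdr (740.3), the phosphate transporter gene Slc34a1 (167.2), the acyl-CoA synthetase gene Acsm2 (160.9), the proton pump subunit gene Atp6v1g3 (90.05), the sodium channel subunit gene Scnn1b (82.18), the intercalated cell transporter gene Slc4a9 (37.48), the carboxylesterase gene Ces1f (30.98) and the calcium channel gene Trpv5 (28.91).

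Female 3 was highest among females for summed intercalated (110.3 CPM) and stromal (193.6) markers, Atp6v1g3 (37.49), the early response gene Ier3 (470.8) and the cholesterol synthesis genes Hmgcs1 (240.7) and Msmo1 (215.1), and lowest for the noncoding RNA Ftx (22.17). Female 4, with the highest background, stood apart with its TMM factor (1.591), Eif2s3y (0.8296 CPM), Kap (47.37) and ENSMUSG00000118488 (3.424). Female 5 had the highest proximal tubule sum of the females (342.0 CPM) and the highest Avpr2 (1.632). In female 1 the single count of Usp9y gave 0.0166 CPM. Male 2 was highest for H2-D1 (2226 CPM) and H2-K1 (1947), which present antigens and whose reads are shared with near-identical copies, male 3 for the immune signalling gene Tyrobp (26.19), and male 4 for the endothelial receptor gene Kdr (123.1) and the smooth muscle actin gene Acta2 (33.16). Male 5 had the highest macula densa sum (34.07 CPM) and the lowest Kdm6a (8.369).

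Proximal tubule genes were higher in male libraries, and the tubules were dissected by hand, without sorting of cells. Markers of that tubule not chosen for a sex difference were also higher in males as a set (log2 difference -1.49, exact permutation p = 0.0128), which is consistent with more proximal tubule RNA in the male libraries. Whether the proximal tubule RNA itself also differed between the sexes, as a biological difference would have it, cannot be told apart from this: the log2 ratio of the male-biased sum to the other proximal sum differed by -0.71, with an SD of 0.916 in females and 1.05 in males (exact permutation p = 0.219). In males most of the male-biased sum came from Kap (1176 of 1302 CPM in male 1), so this ratio leans on 1 gene. With the proximal marker mean as a covariate Cyp2e1 (-1.97, adjusted p = 0.0212, edgeR) and Ugt2b38 (-3.42, adjusted p = 0.0182, edgeR) stayed called. With the background as a covariate Cyp2e1 lost its call (edgeR adjusted p = 0.0759), while its fold change lay between -3.52 and -1.97 in all 28 alternatives. The proximal genes known to be higher in females summed to 9.14 CPM in females and 6.02 CPM in males (0.58, exact permutation p = 0.0734, and 0.25, p = 0.249, without the libraries with the highest and lowest background). Without the same 2 libraries the proximal difference was -1.25 (exact permutation p = 0.0281, adjusted p = 0.0985 by Benjamini-Hochberg), which missed the threshold.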

How the results depend on the processing

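The labels do not say that the libraries are of separate animals, so p-values measure the spread between these samples. Of the settings below, the background covariate, the number group covariate (label numbers 1 to 3 against the others), TMM factors from genes at 5 CPM, the omission of the libraries with the highest and lowest background (male 1 and female 4), and the 5 CPM filter for lists were chosen after seeing the data. The count of 189 genes became 509 with DESeq2 (20.2% higher in females, against 5.3%), 305 without a filter, 27 with the 5 CPM filter, which tests fewer genes, 99 with a replicate block and 114 to 221 with 1 library left out. The block fit also leaves out male 7, whose number no female carries. Without male 7 and without the block 114 genes were called, 21 of them autosomal. It was 144 with limma voom, 199 with median-of-ratios factors, 177 with upper-quartile factors, 154 with library totals, 149 with the proximal covariate, 208 with a surrogate variable, 165 with a 1.5-fold threshold, 190 with the background covariate, 271 with the number group covariate, 165 with TMM factors from genes at 5 CPM and 236 without the extreme libraries. The 35 autosomal genes became 150 with DESeq2, 13 with limma voom, 10 with library totals, 53 without a filter, 4 at 5 CPM, 15 with the block, 3 with the proximal covariate, 15 with the 1.5-fold threshold, 24 with the background covariate, 30 with a surrogate variable, 85 with the number group covariate, 16 with TMM factors from genes at 5 CPM and 21 to 49 with 1 library left out. The background covariate kept 6 of the 35 calls and none on the proximal lists (6 before), the surrogate variable 9 and 1, the block 10 and 1, and the number group covariate 19 and 2. Of these 35 genes 1 was called in every alternative and 11 in at least 20, and of the 144 Y-linked genes 18 and 119. With the number group covariate the calls of Ncf4, Ces2c, Slc7a13, Acsm2, Slc34a1, Slc22a12, Ces1f, Ass1 and Slco1a1 ended, and Ppp1r1b, Sostdc1 and Tyrobp were called. With the block those of Ces2c, Slc7a13, Slc22a6, Acsm2, Slc34a1, Slc22a12, Ces1f, Pdzk1, Ass1, Cyp4a12a, Slco1a1, Gata1, Frmpd3, 5330434G04Rik, Gm15256, ENSMUSG00000118488 and ENSMUSG00000118511 ended, and Ppp1r1b and the late distal convoluted and connecting tubule, calcium and hormone receptor lists were called. The 20 lists, 18 lower in females, became 1 with an estimated correlation, 1 with fry, 12 at 5 CPM (11 lower), 23 with the block (21 lower), 21 with the number group covariate (19 lower), 17 with the proximal covariate (15 lower) and 18 to 22 with 1 library left out. With the background covariate 17 lists were called, 8 of them lower in females, and 10 of the 20 calls were kept in their direction. Without the extreme libraries 18 were called, 11 of them lower in females, and 13 of the 20 were kept. With the background covariate the camera direction turned for 12 lists, whose medians on voom values became 0.0444 (early distal convoluted tubule), 0.32 (late distal convoluted and connecting tubule), 0.0405 (principal cells), 0.11 (cotransporter regulators), -0.0638 (magnesium), 0.14 (calcium), 0.48 (corticosteroid targets), 0.18 (clock), 0.55 (early response), -0.0043 (fatty acid oxidation), 0.0373 (endoplasmic reticulum stress) and 0.0384 (glutathione and redox). Of these the late distal convoluted and connecting tubule, regulator, calcium, corticosteroid, clock and early response lists were then called higher in females with the preset correlation (camera adjusted p from 1.29e-09 to 0.0293). Without the extreme libraries it turned for late distal convoluted and connecting tubule (0.26), corticosteroid targets (0.31), early response (0.29), these 3 called higher in females, and endoplasmic reticulum stress (0.0429), not called. The 4 cell type sums called became 0 with library totals, 1 with TMM factors from genes at 5 CPM, 2 without the extreme libraries and 1 to 4 with 1 library left out. Where the construction of a setting does not give the reason, the cause was not tested. No direction of a called gene named here turned. Of the 6 replicate numbers shared by the sexes, females 1 and 5 correlated best with the male of their own number, with correlations from -0.078 to 0.362, so pairs were not shown, and whether the numbers mark a shared batch or day stays open. With the block, and so without male 7, 5698 genes had an unadjusted p under 0.05 (edgeR). It was 2270 without male 7 and without the block, 2386 in the fit of all libraries and 8430 with the number group covariate. In simulated data edgeR recovered 18% of genes changed 2-fold, and recovery was not measured by depth.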

Other observations

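Of the tests below, those of the silent sex chromosome genes, the splits by label numbers and the 5 CPM filter for the lists were chosen after the results were seen, and the genes of the next 2 paragraphs, apart from Fxyd2, Klk1 and Kl, were named after their values were seen.

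With only genes of at least 5 CPM in 6 libraries, 2 autosomal genes well expressed in these tubules passed that did not pass among all tested genes. Sostdc1 (ENSMUSG00000036169, 12: 36314139 to 36318452), which encodes a secreted antagonist of BMP and Wnt signalling, stood at 330 ± 77.3 CPM in females and 565 ± 134 CPM in males, with all 7 male libraries above every female library. Its fold change was -0.54 ± 0.08 in that fit (edgeR adjusted p = 0.005) and -0.78 ± 0.22 among all tested genes (edgeR adjusted p = 0.237). Ppp1r1b (ENSMUSG00000061718, 11: 98348404 to 98357796), which encodes a regulator of protein phosphatase 1 and is on the thick ascending limb list, stood at 66.7 ± 15.6 and 119 ± 29.2 CPM, with -0.59 ± 0.10 (edgeR adjusted p = 0.0211) and -0.83 ± 0.21 (edgeR adjusted p = 0.127). Of the 28 alternatives, Sostdc1 was called in 5 and Ppp1r1b in 8. The unnamed gene Gm37924 was called in all 28, at 5.75 ± 1.58 CPM in females and 35.8 ± 12.8 CPM in males (-2.64 ± 0.29, edgeR adjusted p = 8.71e-06).

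Several other genes did not pass over all genes. Kap, whose transcript in proximal tubules is regulated by androgens, stood at 12.2 ± 17.3 CPM in females and 273 ± 422 CPM in males (edgeR adjusted p = 0.311), and Tyrobp, a signalling adaptor of myeloid cells, at 6.43 ± 2.48 and 14.8 ± 5.41 CPM (-1.20 ± 0.28, edgeR adjusted p = 0.0547). With 1 library left out, Tyrobp was called without female 3 or male 1. Fxyd2, which encodes the gamma subunit of the sodium pump, was among the most abundant transcripts at 6747 and 10299 CPM (-0.61 ± 0.27, edgeR adjusted p = 0.651), Klk1 stood at 2643 and 3393 CPM (-0.36 ± 0.32) and Kl, which encodes the FGF23 coreceptor klotho, at 1417 and 1523 CPM (-0.10 ± 0.30). Signs of Klk1 and Kl turned with library totals (-0.33 and -0.26 relative to the median of all genes) and with the background as a covariate.

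Reads fell on silent genes of the sex chromosomes. On 146 X-linked unprocessed pseudogenes the rate over that of 1742 autosomal ones was 0.645 ± 0.0819 in females (SD, n = 6) and 0.284 ± 0.0477 in males (SD, n = 7), a log2 difference of 1.19 (exact permutation p = 0.000583, the smallest the 1716 splits can give), near the doubling that the number of X chromosomes would give. This difference is near what genomic DNA in the libraries would give, but the levels did not follow copy number. In females, with 2 copies of X as of each autosome, the rates were not equal. In males, with 1 X and 1 Y, the ratio was 0.665 ± 0.117 (SD, n = 7) on Y-linked unprocessed pseudogenes against 0.284 on X. The reason was not tested. For this class the difference between the sexes argues against low-level transcription across the genome, since 1 X is inactive in females and the difference would then lie near 0. Female reads on 488 Y-linked unprocessed pseudogenes, at 0.00506 of the male rate, argue against reads shared with copies on other chromosomes for this class. The 9 X-linked receptor genes differed by 0.09 (exact permutation p = 0.0676), nearer to the value for transcription than to a doubling. Of them 1 took 72% of their counts, without which the difference was 0.38 (exact permutation p = 0.0291). On 897 X-linked processed pseudogenes the log2 difference was 0.73 (exact permutation p = 0.000583). Both pseudogene classes were limited to genes under 3 CPM per kb. The classes thus differ, and genomic DNA is not shown for receptor genes, nor do the levels settle it for unprocessed pseudogenes. On 65 processed Y-linked pseudogenes the female rate was 0.169 of the male rate (0.427 against 2.53, relative to autosomal ones), so shared reads stay open for that class, as does transcription from the Y chromosome, a biological difference between the sexes, for single Y genes.

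Of the 3 autosomal genes called higher in females, 2 lie within 100 kb of Pvalb, where 7 genes were tested. Deviations of Ncf4 and Gm49694 from the sex means ran together with r = 0.953 (permutation p = 0.00101, adjusted p = 0.00101 by Benjamini-Hochberg over 3 relations) and rho = 0.692 (permutation p = 0.0147), with r = 0.832 without the 2 libraries farthest from the median, 0.99 within females and 0.935 within males. The value within males leans on male 1, at 1.34 and 2.05 CPM. The other males lay between 5.65 and 10.5 CPM for Ncf4 and between 8.49 and 13.6 CPM for Gm49694. An r within males without male 1 was not computed. The joint course could arise from a differing dose of the Pvalb-tdTomato transgene and of sequence beside it. Such a dose could differ with the number of copies an animal carried, but the sources used here do not give the span of the transgene. The other tested genes of the region do not decide whether a dose reaches all of it. Pvalb (-0.42) and Ift27 (-0.49) lay lower in females, and Csf2rb2 (0.40), Cacng2 (0.49) and A730060N03Rik (0.20) higher. None was called, but in simulated data edgeR recovered only 18% of genes changed 2-fold. A biological difference between the sexes, with both genes under shared control, stays open and was not tested.

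Of 18 list calls outside the sex chromosome lists, 10 were kept in the same direction with genes under 5 CPM left out (9 to 12 with 1 library left out), and of the 16 lists that could still be tested 6 lost their call. Sex labels were also set aside and 100 splits of the libraries into 6 and 7 were compared, the real split among them. For the 189 genes only 1 of the 100 splits, the real one, reached as many, with at most 5 in any other, but 144 of these genes are Y-linked and present in males alone, so the design sets the real count high, and the comparison says nothing about chance. For the 35 autosomal genes only 1 of the 100, the real split, reached as many, with at most 4 in any other, in splits that take no account of label numbers. The Y-linked calls of the real split also ease the adjusted threshold for its autosomal genes, so this comparison does not exclude chance either. For the 20 lists, 33 of 100 splits reached as many, with up to 25 in another, so chance was not excluded. With genes of at least 5 CPM the 27 calls, and the 4 autosomal ones among them, were reached by 2 of 100 splits, with 45 and 44 in the other. That other split put 1 of the 6 libraries with label numbers 1 to 3 on its side of 6. The other drawn splits with that share gave at most 1 call at 5 CPM, so what lies behind its count of 44 is not known.

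A split that was not among the 100, libraries with label numbers 1 to 3 in both sexes against the 7 others, gave many more calls than the sexes: 5841 genes, 5675 of them autosomal, and 21 lists (edgeR and camera, Benjamini-Hochberg), and 2701 genes with the 5 CPM filter. Within females alone the same split called 2653 genes and within males 1534, with 510 in both, and fold changes ran together over 33634 genes (r = 0.558, rho = 0.644). The background was lower in the libraries numbered 1 to 3, by 1.04 log2 units (exact permutation p = 0.00117). Kdm5c stood at 48.9, 48.4, 33.3, 16.2, 17.8 and 20.5 CPM in females 1 to 6 and at 46.2, 44.0, 30.3, 14.7, 14.8, 14.5 and 14.4 CPM in males 1 to 7. The labels give no batch, day or animal for the numbers, and nothing that would explain the split was tested. Of each sex 3 libraries carry numbers 1 to 3, and with this grouping as a covariate 85 autosomal genes differed between the sexes (edgeR, Benjamini-Hochberg). Of 700 splits that keep 3 libraries of each group numbered 1 to 3 and 4 or more on the side of 6, 100 were compared, the real one among them. Only 1, the real one, reached 85 with the covariate, with at most 2 in any other, and without the covariate only the real one reached 35, with at most 1 in any other. These counts do not exclude chance for the autosomal genes. The adjustment ran over all genes, and Y-linked genes differ in the real split by design. Their calls ease the threshold for autosomal genes in that split alone. How much of the gap this makes was not tested, and which genes are called depends on the setting.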
